A study of Mus musculus with 12 samples.

How the data were processed

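The assay was CRE-seq, a massively parallel reporter assay in which each candidate regulatory sequence is cloned next to a promoter and is read out through short barcodes in the reporter transcript. Per the labels' protocols, elements of 100 bp stood upstream of either a rhodopsin promoter (pRho) or a Crx promoter (pCrx) driving the red fluorescent reporter DsRed, with barcodes of 13 bp in its 3' untranslated region. Whole retinas of newborn CD1 mice were electroporated with 30 micrograms of 1 plasmid library and 30 micrograms of a GFP plasmid and were kept as explants for 8 days. A replicate was a pool of 5 retinas, and each promoter had 3 replicates. Barcodes were amplified from cDNA and from DNA by 21 and then 6 cycles of PCR and sequenced with reads of 50 bp. No molecular identifiers are mentioned, so reads are not independent molecules, and errors from counting cover counting alone.

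The deposited count table holds raw read counts per barcode for 12 libraries, as whole numbers with totals that differ between libraries. The aligner or counter is not given in the sources used here; the genome build, mm9, is named in the submitters' processing notes. The deposited expression table holds log2 values of cDNA over DNA per element. Its 3 replicates of a promoter hold nearly the same values once sorted, which is what quantile normalization between replicates gives; no header of the authors' files states the method. The authors' deposited table of comparisons between modified and unmodified elements gives log2 fold changes with p-values and adjusted p-values. Its p-values equal those of a Welch test of the replicate values and its adjusted ones a Benjamini-Hochberg adjustment over both promoters, as recomputed from the values; no header states either. The results start from the counts, and the authors' deposited table is used only for a comparison.

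The table of designed sequences assigned all 100000 barcodes to 14987 different elements, with 6 barcodes for 4909 elements and 7 for 10078. Each element is the central 100 bp of a named region of 200 bp, so element positions were taken 50 bp inside the region, 1-based in mm9. Positions of changed bases count from 1 at the first base of the element. A token such as A9C gives the unmodified base, its position and the new base; each token was recomputed from the unmodified and modified sequence, and 0 differed. There were 1270 unmodified elements and 13717 modified ones, each with its unmodified parent. For 17 regions the unmodified sequence had been named as a spacer variant; these were counted as unmodified. The gene annotation at hand was of another genome build, so elements were not assigned to genes and the gene lists prepared for that purpose were not used. No element was named as a control, so no comparison with control elements was made.

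Homeodomain sites of the K50 type read TAATCC or a close relative, and those of the Q50 type TAATTA or a relative; the names refer to the amino acid at position 50 of the homeodomain. Inactivating changes in K50 sites replaced the second A of TAAT, or the A at that place in a relative such as TAAG, by C. A dimer site holds a pair of such sites in opposite orientation, called its arms here. In 2 further sets of 100 elements each, windows of 13 bp around a dimer or a monomer site were changed base by base. These windows were oriented so that the TAATCC-like sequence starts at position 2. The first core covers positions 2 to 5, the spacer 6 to 8, the second core 9 to 12 and the flanks 1 and 13. Positions 6 and 7 are where TAATCC has its CC, so changes in the spacer can also change that site. Some single-base changes of the windows are named in other series and were counted there. Of 300 possible changes per position this left 225 at position 4 of dimer sites, where 72 belong to the series of inactivated sites and 3 are absent. Through the spacer series it left 272, 158 and 126 at positions 6, 7 and 8 of dimer sites, and 206 and 57 at positions 7 and 8 of monomer sites. At positions 7 and 8 these cover 72 and 95 dimer sites, and at position 8 they cover 56 monomer sites. In monomer sites 8 changes at position 4 are absent. Means over all single-base changes of the windows were added as an alternative after seeing the data. Deletions and insertions kept the element at 100 bp by taking in or leaving out genomic bases downstream.

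Counts were summed over the barcodes of an element. Elements needed at least 10 DNA counts in each DNA library, which all 14987 passed. Element activity was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM normalization) as cDNA against DNA in the 6 libraries of a promoter, so activity is relative to the typical element of the library and not to an empty promoter. The promoter difference was the interaction of promoter and cDNA against DNA over 12 libraries. A variant effect was the interaction of allele and cDNA against DNA for a modified element and its parent, and its promoter difference the corresponding triple interaction. Each of the 6 comparisons was adjusted on its own by Benjamini-Hochberg over all elements or pairs at 0.05. Errors marked SE come from these fits. Means over sites or elements were compared by two-sided permutation tests with 100000 resamples, whose smallest possible p is 1e-05; sites are not replicate retinas, and variants of one element share the error of their parent. The motif list, the contrast of dimer and monomer sites, the 6 comparisons and the rule for named items were fixed before the data were examined. The orientation of the site windows and tests of site parts, spacing, spacer sequence, additivity, promoter differences per class and all tests with barcodes as units were chosen after seeing the data.

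Named items were chosen by that rule. Among unmodified elements past the threshold and of 1 sign in all 3 replicates, these are the 10 highest and 5 lowest for each promoter and for the promoter difference. Among variants they are the 10 largest falls and 5 largest rises per promoter, with at most 1 variant per parent.

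Same-numbered cDNA and DNA libraries came from 1 pool of retinas, so the replicate number pairs them by design. The correlations of their deviations from the group means lay between -0.036 and 0.051, and the fit with a replicate block was run as an alternative. Replicates of a group differed by more than sampling noise, with chi-square per degree of freedom from 4.60 to 22.7, so none were merged. All replicates of a promoter carry the same barcodes, so the spread between pools does not include differences between barcodes. A limma 3.58.1 test on log2 ratios per barcode, with libraries summed and a pseudocount of 1, was therefore added with barcodes as units; it used barcodes with at least 30 DNA reads, 97.8% of them for pRho and 97.3% for pCrx. The other alternatives were the replicate block, no filter and a filter at 50 DNA counts, leaving out each replicate and leaving out the barcode with the highest ratio. Limma on replicate log2 ratios, DESeq2 1.42.0, total-count scaling, medians in place of means and parents above the median activity were also used. For motifs, a linear fit of activity on GC content alone was subtracted before the test. Chosen after seeing the data, 1 value per element was used in place of sites. Permutation tests and summaries used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

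The models were tested on simulated counts with 200 changed items. These counts used the element shares of the DNA libraries, the real library sizes and 1 common dispersion per promoter. For element activity (14987 elements), changes of 1.5-fold were recovered for 100% of changed elements on pRho and 95.5% on pCrx. For variant effects (13717 pairs), they were recovered for 100% on pRho and 56.7% on pCrx, and changes of 2-fold for 100% on both. For the promoter difference in variant effects, 22.4% of changes of 1.5-fold and 88.1% of changes of 2-fold were recovered. Barcodes as units were tested on simulated log2 ratios with an assumed spread between barcodes, not on counts. There, 26.9% of variant effects of 1.5-fold and 91.0% of those of 2-fold were recovered. False calls numbered from 4 to 13 per comparison. The simulated counts held no differences between barcodes of one element, so these numbers leave out calls from that source. In the real counts, 2 groups of 3 barcodes of the same element were called different for 17.2% of elements on pRho and 4.62% on pCrx.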

Results

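The activity of 14987 DNA elements of 100 bp was measured in mouse retinal explants, upstream of a rhodopsin promoter (pRho) and of a Crx promoter (pCrx). Rhodopsin is the light-sensing pigment of rod photoreceptors, and Crx is a homeodomain transcription factor of photoreceptors and some bipolar cells. Of these elements, 1270 were unmodified genomic sequences and 13717 were modified versions, most with changes in homeodomain binding sites. The design thus asks which sequences are active on each promoter and how much of that activity depends on single sites. Each promoter had 3 replicates, each a pool of 5 retinas with a cDNA and a DNA library. Library totals were 31408642 to 35737181 DNA reads and 27614797 to 31842705 cDNA reads on pRho, and 31198771 to 36500857 and 24726849 to 27659982 on pCrx. The median element had between 1219 and 2328 reads per library. Log2 activity correlated between replicates across elements at r = 0.979 to 0.985 for pRho and 0.949 to 0.955 for pCrx; elements are not independent replicates.

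Unmodified elements spanned a wide range of activity on both promoters. On pRho, 614 were more active than the typical element, 523 were less active and 133 did not pass the test; on pCrx these numbers were 631, 395 and 244 (edgeR, adjusted together over 14987 elements). The SD of log2 activity over elements was 1.12 on pRho and 1.02 on pCrx, against median SEs of 0.08 and 0.10. Elements at the 95th percentile were 12.7-fold more active than those at the 5th on pRho and 9.69-fold on pCrx. The most active element on both promoters was chr14:52727841-52727940, with log2 activity of 2.29 ± 0.07 on pRho and 2.77 ± 0.08 on pCrx (SE, n = 3 replicates, edgeR), or 4.90-fold and 6.82-fold above the typical element. Its sequence is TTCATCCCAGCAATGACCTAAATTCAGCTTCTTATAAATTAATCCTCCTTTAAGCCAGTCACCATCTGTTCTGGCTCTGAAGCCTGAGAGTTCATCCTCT. On pRho it was followed by chr10:80876714-80876813 at 2.18 ± 0.07, chr15:103164816-103164915 at 2.10 ± 0.10, and chr18:56764919-56765018 at 2.07 ± 0.07 (SE). On pCrx it was followed by chr8:61013519-61013618 at 2.71 ± 0.10, chr4:139687655-139687754 at 2.66 ± 0.10, and chr9:123760050-123760149 at 2.52 ± 0.08 (SE).

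The least active unmodified elements lay far below the typical element. On pRho the lowest was chr9:45613185-45613284 at -4.03 ± 0.15, followed by chr4:53789056-53789155 at -3.18 ± 0.12 (SE, edgeR). On pCrx the lowest was chr3:51290891-51290990 at -4.00 ± 0.13, which was also low on pRho at -2.46 ± 0.09 (SE). Its sequence, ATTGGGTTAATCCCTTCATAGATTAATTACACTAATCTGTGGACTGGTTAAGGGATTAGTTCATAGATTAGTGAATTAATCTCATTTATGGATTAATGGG, carries many TAAT sequences on either strand. Over all elements, 6480 passed as higher and 6850 as lower on pRho, and 5608 and 5772 on pCrx. These counts depend on what is taken as typical: with total-count scaling the median log2 activity moved from -0.04 to -0.23 on pRho and from -0.05 to -0.39 on pCrx. The share of higher calls then moved from 49.3% to 32.4% on pCrx.

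Activity on the 2 promoters was related but not the same. Across the 1270 unmodified elements, Pearson's r was 0.727 and Spearman's rho 0.719 (permutation p = 1e-05 for each, the smallest possible), across elements that are not independent replicates. Of the unmodified elements, 574 were relatively more active on pCrx, 295 were more active on pRho and 401 did not pass the interaction test; with barcodes as units as well, 422 and 195 passed. The widest gap was at chr11:88917445-88917544, which lay below the typical element on pRho (-1.66 ± 0.08) and above it on pCrx (1.83 ± 0.09), a difference of 3.50 ± 0.13 (SE, n = 3, edgeR adjusted p = 1.8e-18). Its sequence is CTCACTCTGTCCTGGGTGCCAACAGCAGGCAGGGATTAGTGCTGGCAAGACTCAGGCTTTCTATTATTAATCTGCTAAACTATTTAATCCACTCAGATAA. Differences near 3 log2 units were also seen at chr5:102451137-102451236 (3.04 ± 0.11), chr12:117389144-117389243 (3.02 ± 0.12) and chr7:116147263-116147362 (3.00 ± 0.13). In the other direction, chr7:133940756-133940855 was above the typical element on pRho (1.08 ± 0.05) and below it on pCrx (-1.10 ± 0.10), a difference of -2.17 ± 0.12. At chr1:132975424-132975523 the values were 1.76 ± 0.07 on pRho and 0.14 ± 0.10 on pCrx (SE). Over all 14987 elements 10254 passed the test, 60.0% of them higher on pCrx. That share was 49.6% with total-count scaling, 51.3% without the barcode of highest ratio and 50.7% without pCrx replicate 1, so the balance between directions was not kept under these settings.

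**Figure D1:**
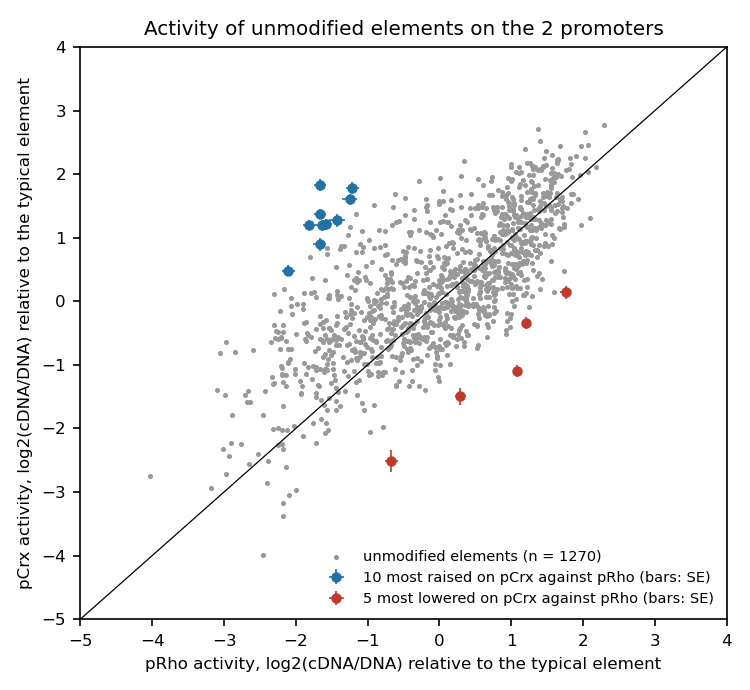
Log2 activity (cDNA over DNA, relative to the typical element) of the 1270 unmodified elements on pRho (x axis) and pCrx (y axis); the line marks equal activity. Coloured points with SE bars are the 10 elements most raised and the 5 most lowered on pCrx against pRho, from a difference of 3.50 down to -2.17.

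Sequence motifs fixed in advance were compared between unmodified elements with and without them, in 22 tests adjusted together. Elements with a NEUROD-type E-box (CAKATG, a sequence bound by neurogenic basic helix-loop-helix factors) were more active on both promoters. The difference was 0.44 on pRho (0.36 ± 1.17 in 143 elements against -0.07 ± 1.11 in 1127, SD, permutation adjusted p = 0.000147) and 0.44 on pCrx (adjusted p = 0.00011). Elements with an MEF2 site were more active on pRho by 0.59 (32 elements, permutation adjusted p = 0.0147), and the difference of 0.45 on pCrx did not pass (adjusted p = 0.0608). The short sequence CCCTC, listed as a CTCF core, went with higher activity on pRho by 0.32 (379 elements, permutation adjusted p = 0.00011). After a linear fit on GC content was subtracted from activity, the difference was 0.18 (permutation adjusted p = 0.0380). That fit did not include the motif. On pCrx the CCCTC difference of 0.08 did not pass. The CRX-like site TAATCC was present in 809 elements, and its differences of 0.15 on pRho and 0.04 on pCrx did not pass (permutation adjusted p = 0.0726 and 0.573). The palindromic dimer TAATNNNATTA, in 35 elements, gave -0.20 and 0.01, and neither passed. Elements without these sequences can hold other homeodomain sites. Such sites were inactivated in 1077 elements, and the K50 monomer sites included 298 TAATCT and 185 TAAGCC. Both arms of dimer sites were changed in 209 elements. These tests therefore set a given site sequence against a mixed group and do not show whether having any homeodomain site matters. Whether a motif's difference was larger on 1 promoter than on the other was not tested.

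Most sequence changes that passed the test lowered activity. Of the 13717 variants, 5993 fell and 2235 rose on pRho, and 5995 fell and 1467 rose on pCrx (edgeR, adjusted over 13717 pairs). The mean log2 effect was -0.23 ± 0.63 on pRho and -0.32 ± 0.68 on pCrx (SD over variants). All replicates share their barcodes. With barcodes as the units as well, 3287 falls and 795 rises passed on pRho, and 3958 and 682 on pCrx.

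The largest falls removed most of an element's activity. In chr8:41511143-41511242 a deletion of 3 bp within a dimer site, with the first changed base at position 32, turned TTAAGCTAAGAAGCTTAGCCTGG into TTAAGCTAAGCTTAGCCTGGCAT. It lowered activity 10.6-fold on pRho (log2 effect -3.41 ± 0.12, SE, n = 3, edgeR adjusted p = 4.2e-30) and 6.31-fold on pCrx. With barcodes as units its SE on pRho was 0.26 (limma adjusted p = 4.8e-07). The SEs and edgeR p-values of named items come from replicate pools and leave out differences between barcodes. In chr4:139687655-139687754, 1 of the most active elements on both promoters, the 3 changes T10G T47G A86C inactivated all K50 sites and lowered activity 9.73-fold on pRho and 7.39-fold on pCrx. A single change, T61G, in chr4:135789349-135789448 (GCTAAGAGGATTAGCCCTGGG to GCTAAGAGGAGTAGCCCTGGG) gave -3.23 ± 0.12 on pRho and -1.08 ± 0.15 on pCrx (SE). The single change T84G in chr11:78575897-78575996 gave -3.03 ± 0.15 and -1.29 ± 0.21. On pCrx the largest fall came from A84C T90G in a dimer site of chr8:61013519-61013618 (ATAAGAGATAAGAGGATTAGCCAGAGA to ATAAGAGATACGAGGAGTAGCCAGAGA), at -3.35 ± 0.15, or 10.2-fold (SE, edgeR adjusted p = 3.9e-15). On pRho the same change gave -0.80 ± 0.11, which did not pass with barcodes as units (adjusted p = 0.263). The change T81G in chr11:54119023-54119122 gave -3.20 ± 0.14 on pCrx and -2.85 ± 0.12 on pRho. In chr4:115642333-115642432, G45A gave -3.03 ± 0.15 on pCrx and -1.94 ± 0.11 on pRho.

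The 5 largest rises on each promoter came from parents below the typical element on that promoter, with activities between -2.10 and -1.18 on pRho and between -3.05 and -1.47 on pCrx. No element of the library exceeded 2.30 on pRho or 2.90 on pCrx. Rises of this size therefore left almost no room for parents above the typical element, and the low parents are not a separate result. In chr15:53019956-53020055, whose activity was -2.10 on pRho and -3.05 on pCrx, the changes A9C T15G in both arms of a dimer site (TGTATTTAATATGATTAACAGCTTT to TGTATTTACTATGAGTAACAGCTTT) raised activity 8.06-fold on pRho (3.01 ± 0.11) and 14.9-fold on pCrx (3.90 ± 0.21, SE, n = 3, edgeR adjusted p = 6.7e-14). In chr7:135012900-135012999, T31G raised activity 6.23-fold on pRho and 8.46-fold on pCrx. In chr6:31242227-31242326, A72T next to a TAATCC sequence (CCTGAGTAGGATAATCCTGTC to CCTGAGTAGGTTAATCCTGTC) raised it 7.27-fold on pRho, from a parent at -1.18, and 5.49-fold on pCrx, from a parent at 0.33. In chr3:68740169-68740268, T32G A40C T47G raised activity on pRho by 2.34 ± 0.20, while the effect on pCrx was -0.28 ± 0.31 (SE); the promoter difference was -2.62 (edgeR adjusted p = 1.2e-07).

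The mean effect of site inactivation was negative in each K50 class and for single Q50 sites on both promoters, with rises as well as falls in every class. For K50 monomer sites the mean log2 effect was -0.36 ± 0.71 on pRho and -0.45 ± 0.74 on pCrx (SD over 1264 sites), with 730 falls and 208 rises on pRho and 677 and 129 on pCrx. Changing 1 arm of a dimer site gave -0.15 ± 0.82 and -0.40 ± 0.98 (461 variants), and changing both arms -0.22 ± 0.93 and -0.52 ± 1.09 (230 sites). Inactivating all K50 sites of an element gave -0.69 ± 0.97 and -0.68 ± 0.99 (361 elements), leaving 61.9% and 62.5% of the parents' activity on average of log2 values. Q50 sites gave -0.15 ± 0.64 and -0.19 ± 0.67 (229 sites), a smaller mean effect than K50 monomer sites on both promoters (difference 0.22 and 0.26, permutation adjusted p = 1.6e-05 for each over 8 tests). All Q50 sites together, in 17 elements, gave 0.14 ± 1.04 and -0.04 ± 0.97.

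The contrast fixed in advance set both arms of dimer sites against monomer sites. On pRho the mean effect was weaker for dimers, by 0.14 (permutation p = 0.00735; 0.14 ± 0.01 over the 3 replicates, SD). On pCrx the difference was -0.07 and did not pass (permutation p = 0.229). The result depended on parent activity. Among parents above the median activity the pRho difference turned to -0.049 (permutation p = 0.464), and the pCrx difference became -0.28 (permutation p = 1e-05, the smallest possible). By medians in place of means the pCrx difference was -0.19 (permutation p = 0.00514). The difference between promoters in this contrast was -0.21 (permutation p = 7e-05), a test chosen after seeing the data.

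**Figure D2:**
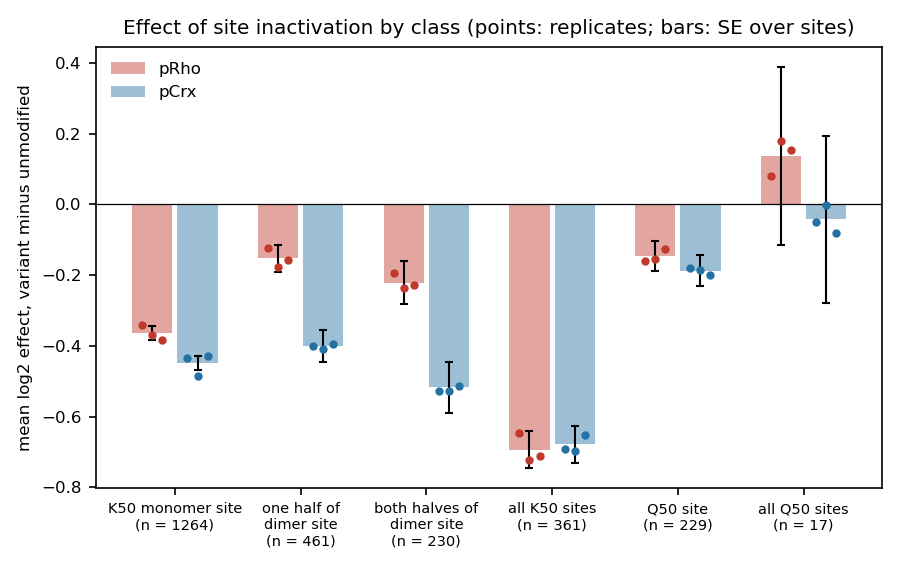
Mean log2 effect (modified minus unmodified element) of inactivating each class of site on pRho and pCrx. Columns are means over sites, points are the 3 replicates and error bars are SE over sites; both arms of a dimer gave -0.22 on pRho and -0.52 on pCrx, against -0.36 and -0.45 for monomer sites.

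Combined changes were set against the sum of their parts and, for dimers, also against the mean single arm, in 6 tests chosen after seeing the data. On pCrx, changing both arms of a dimer lowered activity by less than the sum of both single arms, -0.52 against -0.80 (difference 0.29 ± 0.90, SD over 230 sites, permutation adjusted p = 2e-05). Inactivating all K50 sites likewise gave -0.65 against a sum of -1.02 for the single sites (difference 0.37 ± 0.89, 322 elements, adjusted p = 2e-05). On pRho the differences from the sum were 0.08 (adjusted p = 0.122) and 0.01 (adjusted p = 0.840) and did not pass. Both arms of a dimer had a lower mean effect than the mean single arm on both promoters. The difference was -0.07 ± 0.38 on pRho (permutation adjusted p = 0.0094) and -0.12 ± 0.35 on pCrx (adjusted p = 2e-05, SD over 230 sites). The difference between promoters in additivity was not tested.

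Base-by-base changes located the sensitive positions of the sites. In both sets of 100 elements the deepest mean effect lay at position 4, the second A of TAAT. It was -0.53 ± 0.82 on pRho and -0.70 ± 0.86 on pCrx in dimer sites, and -0.39 ± 0.75 and -0.51 ± 0.78 in monomer sites (SD over 100 sites). The dimer values rest on 225 of 300 possible changes; with 72 more that the series of inactivated sites names, they were -0.55 and -0.71. In monomer sites position 3 was close to position 4, at -0.38 ± 0.56 on pRho and -0.48 ± 0.63 on pCrx. The order of positions was not tested. In the first core (positions 2 to 5) dimer and monomer sites had mean effects of -0.37 and -0.30 on pRho and of -0.50 and -0.44 on pCrx, differences that did not pass (permutation adjusted p = 0.517 and 0.518, 8 tests). In the second core (positions 9 to 12) dimer sites were more sensitive: -0.23 ± 0.43 against -0.04 ± 0.21 on pRho (adjusted p = 0.00028) and -0.38 ± 0.51 against -0.11 ± 0.24 on pCrx (adjusted p = 0.00024). There, 558 of 1197 dimer variants and 258 of 1200 monomer variants fell on pRho, and 609 and 252 on pCrx. With barcodes as units as well, 17.3% to 30.6% of dimer changes per position fell on pRho, and 3.67% to 6.33% of monomer changes. On pCrx these shares were 24.7% to 46.1% and 6.00% to 10.3%. In the spacer (positions 6 to 8) the dimer mean was lower on pCrx, -0.41 against -0.25 (adjusted p = 0.0366), and the difference on pRho did not pass (adjusted p = 0.0976). The pCrx difference did not pass without replicate 2 or without replicate 3 (adjusted p = 0.0573 and 0.0533). It was not kept either when single-base changes named in the spacer series were included: -0.26 ± 0.40 against -0.21 ± 0.30 (SD, 100 elements each, permutation adjusted p = 0.403). In the flanks (positions 1 and 13) dimer and monomer means were -0.02 and -0.01 on pRho (adjusted p = 0.738). On pCrx they were -0.01 and -0.11, and the monomer mean was lower (permutation adjusted p = 0.0366), though not past the threshold without replicate 2 (adjusted p = 0.0773).

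**Figure D3:**
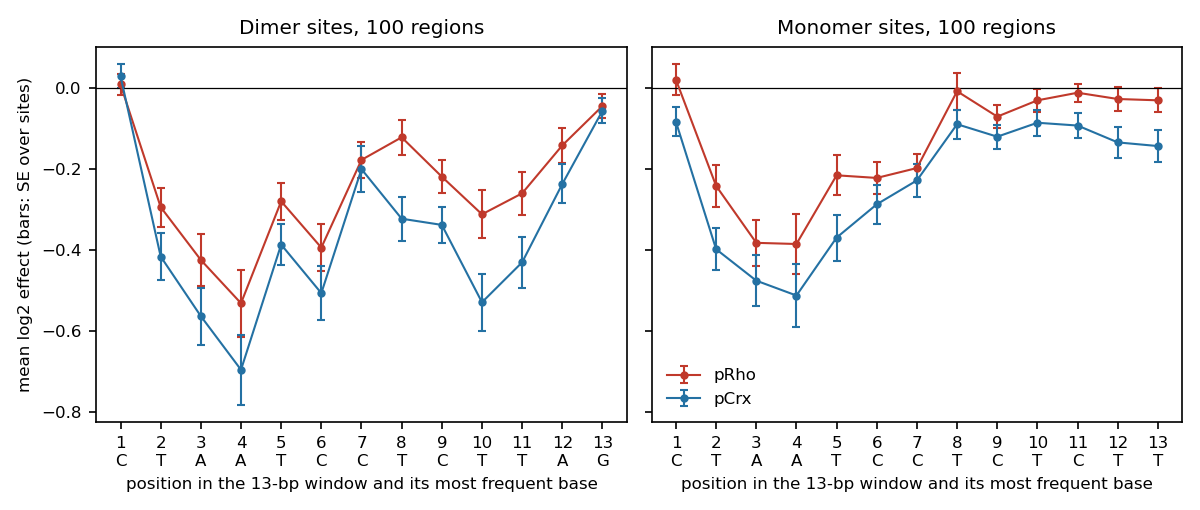
Mean log2 effect of single-base changes by position in the 13-bp window of dimer sites (left) and monomer sites (right), with the most frequent base under each position and SE over sites. Both sets are lowest at position 4; effects at positions 9 to 12 average -0.23 (pRho) and -0.38 (pCrx) in dimer sites, against -0.04 and -0.11 in monomer sites.

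Deletions and insertions after the first core had lower mean effects in dimer sites than in monomer sites, in 12 tests chosen after seeing the data. All 12 tests used the same 2 sets of elements. A deletion there can also remove the CC of TAATCC, as in chr7:86292431-86292530, so length and site sequence can change together. Monomer windows have no fixed second core: at positions 9 to 12 the most frequent base was in 33% to 52% of sites. The 2 sets are different elements. On pCrx, dimer parents had mean activity of 0.44 against 0.29 for deletions and 0.45 against 0.31 for insertions, which was not adjusted for. Deletions of 3 bp gave -0.52 ± 0.92 in dimers and -0.23 ± 0.72 in monomers on pRho, and -0.61 ± 0.86 and -0.31 ± 0.65 on pCrx (SD over 100 elements). Insertions of 1 bp gave -0.27 ± 0.72 against -0.03 ± 0.37 on pRho, and -0.44 ± 0.68 against -0.06 ± 0.37 on pCrx. Insertions of 3 bp gave -0.26 ± 0.79 against 0.10 ± 0.54 on pRho, and -0.41 ± 0.72 against 0.01 ± 0.49 on pCrx. All 12 differences passed, with permutation adjusted p from 4e-05 to 0.0143. Activity also differed between spacer sequences: across 12 spacers placed in each dimer element, mean log2 activity spanned 0.39 on pRho and 0.75 on pCrx (permutation p = 1e-05 for each, the smallest possible). In dimers CGG was highest, at 0.18 on pRho and 0.37 on pCrx relative to the mean of the 12 spacers, followed by CCG at 0.15 and 0.30. TGG was lowest, at -0.20 and -0.38. In 84 monomer elements the span was 0.31 and 0.41 (permutation p = 1e-05), with CCG highest (0.16 and 0.23) and AGG lowest (-0.15 and -0.17). Monomer windows held C at position 6 in 100% and at position 7 in 98% of sites, as part of TAATCC. CCG keeps this CC and AGG does not. Spacers without CC also change the site, so these spans do not show a preference for spacer sequence alone.

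**Figure D4:**
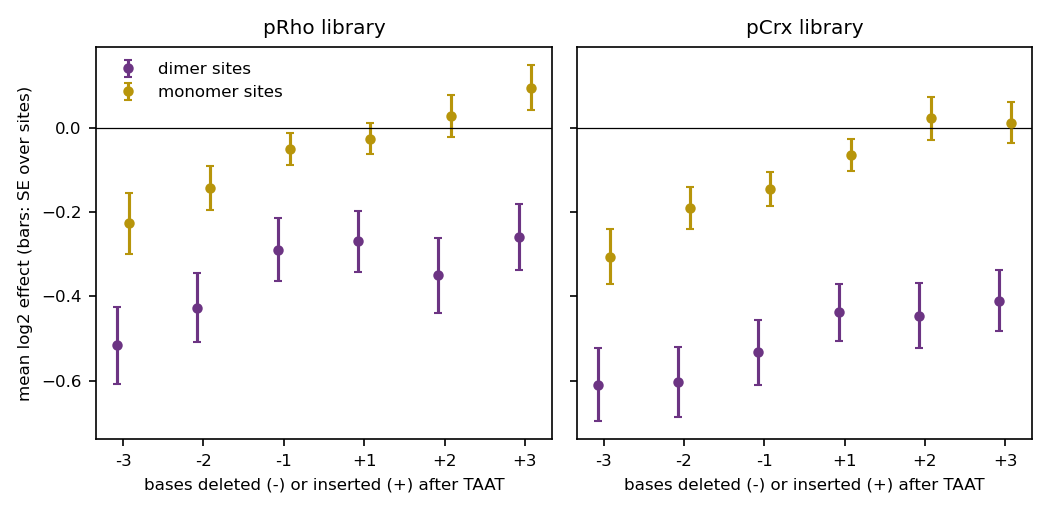
Mean log2 effect of deleting or inserting 1 to 3 bp after the first core in dimer and monomer sites on pRho (left) and pCrx (right), with SE over elements. Dimer means lie between -0.26 and -0.61, below the monomer means at every change of length. Deletions can also remove the CC of TAATCC.

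Variant effects differed between promoters for 5323 of 13717 variants, 3246 of them lower on pCrx and 2077 higher (edgeR triple interaction); with barcodes as units as well, 1432 and 566 passed. Among variants past the test on both promoters, 3933 fell on both and 730 rose on both, against 2619 and 239 for independent lists of these sizes. Another 640 went in opposite directions, fewer than the 1618 of independent lists; for 138 of them both effects also passed with barcodes as units. Across 13717 variants the effects correlated between promoters at r = 0.541. With odd barcodes on pRho and even ones on pCrx, so fewer barcodes per value, r was 0.439, while the covariance was 0.245 against 0.232 with all barcodes; within a promoter, separate barcodes gave 0.691 on pRho and 0.706 on pCrx. Many variants share a parent, so they are not independent. By class, the mean over elements of the pCrx effect minus the pRho effect was -0.26 for both arms of dimers (permutation adjusted p = 0.000665 over 19 tests) and -0.23 for 1 arm (adjusted p = 0.000665). Over all variants it was -0.05 (adjusted p = 0.0237) and for single bases of the monomer set -0.10 (adjusted p = 0.0267). For K50 monomer sites it was -0.05 (adjusted p = 0.0579) and for all K50 sites 0.01 (adjusted p = 0.790), and neither passed.

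The authors' deposited table covered 13176 variant comparisons per promoter. On pRho it listed 3706 falls and 1137 rises at an adjusted p under 0.05, and on pCrx 3622 and 620. Its log2 fold changes correlated with those of the pair model across variants at r = 0.985 and 0.984. Of the 4843 variants that the authors' deposited table called on pRho, 4724 also passed the pair model, and of its 4242 on pCrx, 4126 did; the pair model called more of the same comparisons, 7906 on pRho and 7169 on pCrx. Of those that passed in both, 4723 had the same sign on pRho and 4126 on pCrx.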

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

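For the patterns below, the counts over other splits of the libraries, the comparison of barcode groups, the sampling of reads, the scaling of pRho effects and all tests with barcodes as units were chosen after the results had been seen, as was the test of the site classes between promoters.

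Activity relative to the typical element differed between promoters for 10254 of 14987 elements by the interaction test, and variant effects differed for 5323 of 13717. In the named elements a tested difference between promoters drew attention. Activity on pCrx minus that on pRho was 3.50 at chr11:88917445-88917544, 3.04 at chr5:102451137-102451236, 3.02 at chr12:117389144-117389243, 3.00 at chr7:116147263-116147362 and 2.86 at chr19:29588019-29588118. It was 2.84 at chr3:65415616-65415715, 2.80 at chr13:54391651-54391750, 2.71 at chr17:27570392-27570491, 2.59 at chr17:8313817-8313916 and 2.57 at chr19:3353971-3354070. It was -2.17 at chr7:133940756-133940855, -1.83 at chr13:98005161-98005260, -1.78 at chr7:128103854-128103953, -1.61 at chr1:132975424-132975523 and -1.54 at chr17:66819032-66819131.

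For 22 named variants the effect on pCrx minus that on pRho passed the triple interaction test with replicate pools as units, and 14 of these also passed with barcodes as units. The 8 others, at adjusted p from 0.060 to 0.293 over barcodes, lie in chr8:41511143-41511242, chr15:53019956-53020055, chr4:44041516-44041615, chr4:115642333-115642432, chr2:167985072-167985171, chr19:42645972-42646071, chr14:48846549-48846648 and chr5:137517461-137517560. Among the largest falls on pRho it was 0.75 for the 3-bp deletion in chr8:41511143-41511242, 2.15 for T61G in chr4:135789349-135789448, 1.19 for the 3-bp deletion in chr4:41581825-41581924 and 1.04 for A50C A68C in chr8:75754210-75754309. It was 1.74 for T84G in chr11:78575897-78575996, 0.99 for T64G in chr6:30690143-30690242, 1.41 for the 2-bp deletion in chr13:44327013-44327112 and 1.80 for the 3-bp deletion in chr7:86292431-86292530. Among the rises on pRho it was 0.89 for A9C T15G in chr15:53019956-53020055, -0.96 for the 3-bp deletion in chr4:44041516-44041615 and -2.62 for T32G A40C T47G in chr3:68740169-68740268. Among the largest falls on pCrx it was -2.55 for A84C T90G in chr8:61013519-61013618, -1.09 for G45A in chr4:115642333-115642432, -0.90 for the 2-bp insertion in chr2:167985072-167985171 and -2.46 for A81C T87G in chr3:126472804-126472903. It was -1.61 for A36C in chr3:96503081-96503180, -0.66 for A65C T71G in chr19:42645972-42646071, -1.70 for T38G T83G in chr9:123760050-123760149 and -1.56 for T81G in chr9:120197264-120197363. Among the rises on pCrx it was 1.11 for A27C T33G in chr14:48846549-48846648, 1.77 for T62G in chr4:147545568-147545667 and 0.82 for T31G in chr5:137517461-137517560.

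Libraries were also split in other ways into groups of the same sizes. There are 10 such splits for each of the 6 comparisons, too few for a share under 0.05, and 1 of 10, the real one, gave as many calls. The real counts were 13330 and 11380 for element activity on pRho and pCrx, 8228 and 7462 for variant effects, and 10254 and 5323 for the promoter differences. The highest count of another split was 0 by edgeR in each comparison. At an unadjusted edgeR p under 0.05 the other splits gave 0 to 1 elements and 0 to 1 variants on pRho, 5 to 17 and 3 to 11 on pCrx, and 23 to 69 and 5 to 26 for the promoter differences. Each other split puts cDNA and DNA libraries, or both promoters, into the same group. The real difference then widens the spread within groups, so these low counts do not measure the rate of false calls.

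More variant effects passed with replicate pools as units than with barcodes as units. When barcodes of each element were divided into 2 groups of 3 and compared over replicate pools, 17.2% of elements on pRho and 4.62% on pCrx were called different, although their sequence is the same. Variant tests sum 6 or 7 barcodes per allele, so these shares are not the share of false calls among variants. The SD of the log2 difference of these groups was 0.43 on pRho and 0.42 on pCrx, at least 4.78 times the 0.08 and 0.09 that counting reads gives, which argues against sampling of reads as the whole source. Differences between barcodes of one element are a candidate source of the surplus, by a test chosen after the counts were seen. No biological explanation was tested.

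Site changes tended to raise activity in elements of low activity and to lower it in active ones. With parent activity and effect taken from separate barcodes, the slope of effect on parent activity was -0.306 ± 0.016 on pRho and -0.517 ± 0.017 on pCrx (SE), which argues against error shared by both. The mean effect in the lowest quartile of parent activity was 0.208 ± 0.049 on pRho and 0.294 ± 0.048 on pCrx, so rises outweighed falls there. A lower limit of measurable activity would block falls and leave rises free. The sign of this mean therefore cannot tell whether such a limit shaped the pattern. In the 200 elements changed base by base, the slope for flank changes was nearer 0 than that for the first core by 0.177 ± 0.026 on pRho and 0.369 ± 0.029 on pCrx. This argues against an equal effect of any sequence change. The flank slopes were themselves below 0, at -0.052 ± 0.016 on pRho and -0.052 ± 0.026 on pCrx, so a smaller effect of other changes is not excluded. For K50 monomer sites, 208 of 1264 changes on pRho and 129 on pCrx passed as rises, 105 and 66 of them with barcodes as units as well. That such sites may lower activity in some elements stays a hypothesis, since it was found and tested on the same data.

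Dimer sites against monomer sites differed between promoters by -0.21 in mean log2 effect. A wider log2 scale on pCrx was argued against, since after scaling pRho effects the dimer mean stayed at -0.202 ± 0.069 (SE, 209 elements). With the parents' own promoter difference as a covariate, from separate barcodes, the class coefficient was -0.0932 ± 0.063, against -0.204 ± 0.066 without it, so parent activity that differs between promoters is a candidate explanation. The promoter itself, which the design names, stays open as a biological explanation and was not tested apart from parent activity.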

How the results depend on the processing

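Tests with barcodes as units were chosen after the data had been seen. They gave 4084 variant effects on pRho, 4667 on pCrx and 2001 promoter differences, against 8228, 7462 and 5323 with replicate pools as units; the cause is weighed with the barcode groups. Among parents above the median activity the contrast of dimer and monomer sites was -0.049 on pRho, a reversed direction that did not pass, and -0.28 on pCrx, which passed; by medians it was -0.19 on pCrx, which passed. By medians position 4 stood at -0.64 on pRho and -0.82 on pCrx in dimer sites and at -0.46 on pRho in monomer sites; the cause was not tested for these. With a replicate block the counts were 13335 and 11361 for element activity, 10188 for its promoter difference, 8431 and 7578 for variant effects and 5491 for their promoter difference, and the replicate block changed no other call among the named items. Leaving out 1 replicate gave 12826 to 13139 and 10496 to 10745 calls of element activity on pRho and pCrx, 9353 to 10098 promoter differences, 6771 to 7693 and 6134 to 6448 variant effects and 4170 to 5215 promoter differences in them. Near 0, 4 results that passed under no setting changed sign; the cause was not tested. The Q50 motif on pRho stood at 0.10 after the fit on GC content was subtracted. Without 1 replicate this motif ran from -0.022 to 0.0028, and all K50 sites minus their sum on pRho from -0.00086 to 0.018. With barcodes as units the 3-bp dimer motif on pCrx stood at -0.076 and the flank contrast of dimer and monomer sites on pRho at 0.011. Over the alternatives run, 540 values of named elements, 300 of named variants and 129 of motifs kept their direction and side of the threshold, and 3 of motifs changed sign; of tested contrasts 150 values kept both, 2 passed only under the alternative, 4 no longer passed and 3 changed sign, with p adjusted in each setting as in the report. On pCrx the spacer contrast of dimer and monomer sites, at -0.17 to -0.15 without 1 replicate, failed without replicate 2 and without replicate 3, and the flank contrast, at 0.087 to 0.12, without replicate 2; the cause was not tested. The spacer contrast also failed at -0.047 with all single-base changes of the window, since these include changes named in the spacer series. Of call counts 71 stayed within 1.5 times the reported count and 3 did not; the majority direction turned in 4 of 68, with shares near 50% in each. Of position means 25 moved by less than 1 SD over replicates and 3 by more. Dropping the filter on DNA counts removed nothing, since all elements passed it. Scaling on control elements and their comparison with genomic elements were not run, since none are named. At this depth counting reads adds an SD of 0.08 to 0.09 to a difference of barcode groups, and simulated variant effects of 1.5-fold were recovered for 56.7% of pairs on pCrx.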

Other observations

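The comparisons of monomer site sequences and site positions below were chosen after the data had been seen, as 4 tests adjusted together. Among K50 monomer sites, changes in TAATCC had the lowest mean log2 effect of the 3 most frequent sequences, -0.46 ± 0.75 on pRho and -0.51 ± 0.75 on pCrx (SD over 676 sites), and 425 and 381 of them fell. Changes in TAATCT gave -0.31 ± 0.65 and -0.35 ± 0.77 (298 sites), and changes in TAAGCC -0.19 ± 0.59 and -0.31 ± 0.59 (185 sites). TAATCC against all other monomer sequences differed by -0.20 on pRho (permutation adjusted p = 4e-05) and -0.14 on pCrx (permutation adjusted p = 0.00158). Sites with the changed base at positions 34 to 67 of the element differed from those elsewhere by -0.09 on pRho (permutation adjusted p = 0.0431) and by -0.04 on pCrx (permutation adjusted p = 0.371).

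GC content of the 1270 unmodified elements had a median of 49% and ranged from 32% to 66%. Across elements, which are not independent replicates, it correlated with activity on pRho at r = 0.193 and rho = 0.173 (permutation p = 1e-05, the smallest possible). On pCrx r was 0.00387 and rho -0.0291 (permutation p = 0.889). The difference between these correlations was not tested. By the number of TAATCC sites, mean log2 activity on pRho was -0.12 ± 1.12 with 0 sites (461 elements), 0.05 ± 1.10 with 1 (681), -0.03 ± 1.24 with 2 (115) and -0.68 ± 1.43 with 3 or more (13 elements, SD). On pCrx it was 0.22 ± 1.00, 0.25 ± 0.99, 0.42 ± 1.16 and -0.48 ± 1.62 (SD); no trend was tested.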
